A study of Homo sapiens with 7 samples.

How the data were processed

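RNA-seq libraries were made with Illumina's TruSeq RNA kit, which does not mark strand, and each of the 7 libraries is one GEO sample. Per the submitters' processing notes, CASAVA 1.8, BWA and Partek 6.6 were used with hg19 (GRCh37), without a stated role for each. Per the file headers, the authors deposited raw read counts for every library over 34917 RefSeq transcripts of 22257 genes. The deposited per-library columns headed FRKM hold log2 values of quantile-normalized reads, as the sorted values are equal in all libraries of a line and each read number has 1 value in a library; they are not divided by transcript length and were not used for tests. Per the file headers, the authors also deposited a log2 ratio of treated to control for each line and, for RL, a p-value and FDR whose test is not stated. The JeKo-1 ratio column is headed as an ALK inhibitor although its sample columns name the BTK inhibitor, and it equals the difference of those columns. A joint table the authors deposited holds a signed fold score (the fold for rises and minus its inverse for falls) for 3536 transcripts of 2056 genes with the same reads, all with an absolute fold of at least 1.5 in at least 1 line; it was not tested further.

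The counts were used as deposited. In 6758 genes with more than 1 transcript, the transcripts largely repeat the same reads (86.7% of these transcripts lie within 10% of the gene's highest count), so they were not summed. All transcripts entered the test, and each gene is reported by the transcript with the highest mean count over the 7 libraries. Summed over all transcripts, the libraries held 41.1 and 44.0 M counts (RL controls), 32.4 and 56.8 M (treated RL), 41.5 M (JeKo-1 control) and 39.5 and 40.7 M (treated JeKo-1), which repeat reads. The 10 highest transcripts held 4.24% to 4.88% of these. Between libraries of a group, counts scattered more than Poisson error, with chi-square per degree of freedom of 3.41 (RL controls), 4.55 (treated RL) and 3.78 (treated JeKo-1) over genes with at least 20 summed counts. CPM were computed over all transcripts with the line's scaling factors.

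Tests used edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment over transcripts, and a gene was called at an adjusted p under 0.05. RL (25099 transcripts tested, 2 residual degrees of freedom) and JeKo-1 (23564 transcripts, 1 residual degree of freedom) were fitted separately, and the difference of effects in a 4-group model of all 7 libraries (26362 transcripts). The common biological coefficient of variation was 4.51% in RL and 3.91% in JeKo-1. Standard errors are the log2 fold change divided by the root of the F statistic. Gene lists (29 lists, 643 entries, 617 distinct symbols, all matched to the deposited symbols) were tested by camera in limma 3.58.1 with a preset correlation of 0.01, for lists with at least 5 tested members, adjusted over lists. Each was also tested with an estimated correlation, and by fry. For JeKo-1 the estimate came from the model of all 7 libraries. Camera's call was lost for every called list with the estimated correlation. With an estimated correlation camera's test has only the residual degrees of freedom of the fit, 2 in RL and 3 in the model of all 7 libraries. A call lost in that test therefore does not show by itself that correlation between genes accounts for the result. The 1-transcript-per-gene table is the basis of list counts and of the correlation across genes, for which 1 pair of lines was compared. Overlaps were tested by Fisher's exact test.

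The lists, the groups, the tests, the alternatives and the rule for named genes were chosen before the data were examined. The rule took, per line, the 10 genes up and 10 down with the largest log2 fold change among called genes averaging at least 5 CPM whose treated libraries lay on one side of all controls, up to 3 members with the smallest p from each list, a fixed set (BTK, MYC, CCND1, EGR1, EGR2, CCL3, CCL4, BCL6, TXNIP, CXCR4, ACTB and GAPDH), the 8 genes with the smallest p of the difference and the 8 with the largest change in both lines. Markers of lineage in untreated cells came from the same lists. Other list members named in the text, MX1 in RL and the neighbours of KLHL21 were chosen after their values were seen. Results of some list members are not reported here.

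The procedures were checked on simulated counts drawn from the real means and library sizes. In each, 200 transcripts were changed, drawn from those above a minimum mean count. In RL (25099 transcripts), 22%, 80%, 94% and 98% of those changed by a log2 fold of 0.25, 0.5, 1 and 2 were called, with 25 of 24899 unchanged ones. In JeKo-1 (23564 transcripts) these were 22%, 66%, 88% and 100%, with 5 of 23364 unchanged, and for the difference (26362 transcripts) 2%, 46%, 82% and 92%, with 7 of 26162 unchanged. In RL the true calls were 11, 40, 47 and 49 of 50 changed transcripts at each size, beside the 25 false ones. False calls thus made up a larger share of the simulated RL calls than the adjusted p threshold allows. The real RL calls may likewise hold more false ones than that threshold states. Camera called the raised list and 0 of 20 unchanged lists in each line. The simulated genes were drawn independently, so this check cannot show how often camera calls unchanged lists of correlated genes.

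Alternatives were DESeq2 1.42.0 size factors in place of TMM, DESeq2's Wald test, limma-voom, no filter and a filter of at least 5 CPM, other thresholds, 1 transcript per gene in the fit, all libraries in one fit, a replicate block, and leaving out each library in turn except the lone JeKo-1 control. Alternatives chosen after seeing the data were the transcript flagged by the authors, and removal of each library's trend with GC content and length, which are known for 94.4% of transcripts. Leaving out a JeKo-1 library used the model of all lines, since the line alone then has no residual degree of freedom. The neighbour order of genes came from the protein-coding genes of a GENCODE annotation of GRCh38 and is given without coordinates. Figures were drawn with matplotlib 3.10.9.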

Results

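RNA was sequenced from 7 libraries of RL and JeKo-1, both described by the submitters as mantle cell lymphoma (MCL) lines, a B-cell lymphoma usually driven by cyclin D1. Cells were left untreated or exposed for 6 h to a BTK inhibitor, named in the series title as ibrutinib, at a dose that is not stated. BTK is the kinase that carries signals from the B-cell receptor (BCR) to calcium, MAP kinase and NF-kB pathways, and ibrutinib binds it covalently. RL had 2 control and 2 treated libraries, and JeKo-1 had 1 control and 2 treated libraries. Reads were counted per RefSeq transcript, and each gene is represented by its most abundant transcript. With 1 transcript per gene, the libraries held 24.2 and 25.9 M counts for the RL controls, 19.1 and 33.5 M for treated RL, 24.4 M for the JeKo-1 control and 23.3 and 24.0 M for treated JeKo-1. Across genes, log2 levels of libraries from the same group correlated with Pearson r of 0.9983 in RL controls, 0.9979 in treated RL and 0.9981 in treated JeKo-1, where genes are not independent replicates. Nothing in the descriptions says that libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Values after ± are standard errors on the log2 scale unless given as SD. Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists from camera with a preset correlation between genes.

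Untreated cells of both lines carried B-cell and mantle cell lymphoma transcripts, at levels that differed between the lines. CCND1, the cyclin D1 gene activated by the MCL translocation, stood at 599 CPM, counts scaled to library size (SD 19.4, n = 2), in RL and 350 CPM in the single JeKo-1 control. SOX11, a transcription factor used as an MCL marker, stood at 169 CPM in RL and 31.6 CPM in JeKo-1, and CD5, a surface marker of most MCL, at 18.6 and 0.0935 CPM. The anti-apoptotic gene BCL2 was at 379 CPM in RL and 33.7 CPM in JeKo-1, and MS4A1, which encodes CD20, at 1455 and 281 CPM. Of the germinal center markers, GCET2 was at 0.620 CPM in RL and 80.8 CPM in JeKo-1, BCL6 at 2.13 and 1.36 CPM, and MME, which encodes CD10, at 19.7 and 14.4 CPM. Of the plasma cell markers, IRF4 was at 305 and 202 CPM and PRDM1 at 28.6 and 2.01 CPM. No test was run between the lines, which differ by origin and have 1 JeKo-1 control.

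Markers of T and NK, myeloid and erythroid cells were low in every library, whereas the epithelial gene EPCAM was expressed in RL. The 16 T and NK cell genes summed to 3.90 to 5.90 CPM over the RL libraries and 0.744 to 2.61 CPM over the JeKo-1 libraries. The 16 myeloid genes summed to 4.61 to 8.92 and 1.24 to 2.25 CPM. The 10 erythroid genes summed to 0.458 to 0.864 CPM in RL and 0.166 to 0.520 CPM in JeKo-1. The 16 epithelial and stromal genes summed to 104 to 109 CPM in RL, of which EPCAM made up 82.1 CPM in the controls, and to 3.30 to 5.17 CPM in JeKo-1, where EPCAM had a count of 0 in all 3 libraries. Few of these genes could be tested. In RL, 1 of 4 T and NK cell genes rose (PRF1), 2 of 6 myeloid genes fell (ITGAX and VCAN; 3 adjusted over the list alone), and of 8 epithelial and stromal genes PECAM1 rose while CDH1 and FN1 fell (1 higher and 3 lower adjusted over the list alone). The myeloid and epithelial lists were not called by camera (adjusted p = 0.121 and 0.859). The FN1 call was lost on leaving out any of the 4 RL libraries, with adjusted p from 0.0676 to 0.144, and in DESeq2's Wald test (adjusted p = 0.219). In JeKo-1, CD28 fell among 2 T and NK cell genes, none of 3 myeloid genes passed (2 lower adjusted over the list alone), PECAM1 rose while PDGFRB and FN1 fell among 3 epithelial and stromal genes, and the 1 erythroid gene tested did not pass.

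In RL treated for 6 h, MYC fell, as did 25 of 32 immediate early genes of BCR signalling and 24 of 30 NF-kB targets. All 35 genes of a MYC target list, most of them for ribosome production, fell as well. With an estimated correlation these lists were not called (adjusted p = 0.0871, 0.0871 and 0.28). Of 28 FOXO targets 17 rose, as did 17 of 30 mitotic genes and all 18 replication histones, lists that had an adjusted p = 0.28 each with an estimated correlation. The chemokine genes CCL4 and CCL3 had the largest falls among genes averaging at least 5 CPM, with log2 fold changes of -3.68 ± 0.11 and -3.37 ± 0.12, from 20.1 to 1.56 CPM and from 16.2 to 1.59 CPM. MYC, a transcription factor that drives growth, fell by 2.55 ± 0.11 on the log2 scale, from 22.3 to 3.76 CPM (adjusted p = 2.9e-08), and the cyclin gene CCND2 fell by 1.79 ± 0.05, from 192 to 55.4 CPM (adjusted p = 3.5e-09). Among called genes averaging at least 5 CPM, the largest rise was that of the taste receptor gene TAS1R1, with a log2 fold change of 3.33 ± 0.14, from 0.967 to 9.80 CPM.

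Of 14932 genes tested in RL, 4543 changed, 2256 upward and 2287 downward, and 228 of the risen and 199 of the fallen genes changed at least 2-fold. After CCL4 and CCL3, the largest falls among genes averaging at least 5 CPM were those of the semaphorin SEMA7A (-3.19 ± 0.12), MYC, the anti-apoptotic BCL2A1 (-2.12 ± 0.08), the MAP kinase phosphatase DUSP2 (-1.87 ± 0.07), the glycosyltransferase GALNT6 (-1.82 ± 0.12), CCND2, the Fc receptor-like FCRL4 (-1.73 ± 0.10) and the activation marker CD83 (-1.72 ± 0.06). After TAS1R1, the largest rises at that level were those of the tetraspanin TSPAN9 (2.29 ± 0.12), SUSD3 (2.13 ± 0.11), the ubiquitin ligase adaptor KLHL21 (2.10 ± 0.08), the sodium pump regulator FXYD6 (1.90 ± 0.06), the telomere-binding ZBTB48 (1.87 ± 0.09), NRN1 (1.86 ± 0.18), the sterol transporter ABCG1 (1.84 ± 0.10), CNPY1 (1.84 ± 0.07) and the fructose transporter SLC2A5 (1.82 ± 0.05). The adjusted p-values of these 20 genes ran from 3.5e-09 to 1.7e-05. CCL3 and CCL4 have near-identical copies, so their reads could be shared between copies. TAS1R1, ZBTB48 and KLHL21 lie side by side in the annotation, and the library kit does not mark strand. BTK itself fell by 0.29 ± 0.05 (adjusted p = 9.8e-04), CCND1 rose by 0.26 ± 0.05 (adjusted p = 0.00153), and BCL6 had a log2 fold change of -0.03 (adjusted p = 0.926).

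Of 32 measured immediate early genes of BCR signalling, 25 fell and 1 rose, NR4A2, with the same counts adjusted over the list alone. Camera gave the list, with a median log2 fold change of -0.944, an adjusted p of 2.9e-26, and an adjusted p = 0.0871 with an estimated correlation. EGR1 and EGR2, transcription factors induced within minutes of BCR engagement, fell by 2.25 ± 0.22 and 1.63 ± 0.23. Of 30 NF-kB targets, 24 fell and 2 rose, REL and CYLD, again with the same counts adjusted over the list alone. CD83, BCL2A1 and the adhesion molecule ICAM1 (-1.49 ± 0.05) were among those that fell (median -0.597; camera adjusted p = 9.1e-33, and adjusted p = 0.0871 with an estimated correlation). CYLD is known as a deubiquitinase that restrains NF-kB.

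All 35 genes of the MYC-linked ribosome production list fell in RL, over all genes and adjusted over the list alone. The list also holds MYC targets with other roles, such as ODC1, CAD, CDK4, TFRC and HSPD1. HSPD1 is also in the heat shock list and TFRC in the housekeeping list. Camera's adjusted p was 2.8e-48, with a list median of -0.639, and it had an adjusted p = 0.28 with an estimated correlation. The nucleolar helicase DDX21 fell by 1.03, MYBBP1A by 1.05 and the pseudouridine synthase DKC1 by 0.89 on the log2 scale. In the heat shock list 12 of 17 fell and 0 rose, as they did adjusted over the list alone, among them the HSP90 genes HSP90AA1 (-0.73) and HSP90AB1 (-0.59) and the co-chaperone FKBP4 (-0.68). Camera gave 2.3e-10, and an adjusted p = 0.28 with an estimated correlation. In the endoplasmic reticulum stress list 13 of 21 fell and 0 rose (1 higher adjusted over the list alone), among them the chaperone HSPA5 (-1.14), PDIA3 (-0.84) and HERPUD1 (-0.65). Camera gave 2.3e-08, and an adjusted p = 0.28 with an estimated correlation. In the cholesterol synthesis list 16 of 24 fell and 1 rose, LSS (2 higher adjusted over the list alone), with falls in HMGCS1 (-0.81) and DHCR7 (-0.74). Camera gave 1.6e-09, and an adjusted p = 0.28 with an estimated correlation.

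Of 28 FOXO targets in RL, 17 rose and 0 fell (19 higher adjusted over the list alone), among them the glucocorticoid-induced TSC22D3 (1.49), YPEL3 (1.35), YPEL5 (0.92) and TXNIP (0.26). Camera gave 4.6e-09, and an adjusted p = 0.28 with an estimated correlation. Of 30 mitotic genes, 17 rose and 0 fell (18 higher adjusted over the list alone), with small changes such as CDC25C (0.71), PTTG1 (0.43) and CCNB2 (0.42). Camera gave 1.2e-05, and an adjusted p = 0.28 with an estimated correlation. All 18 measured replication histones rose, also adjusted over the list alone, by a median of 0.312, with HIST1H1E at 0.48 and HIST1H1D at 0.43. Camera gave 7.7e-11, and an adjusted p = 0.28 with an estimated correlation. Histone genes are near-identical, so their reads could be shared. Of 24 p53 targets, 10 rose and 4 fell (10 and 6 adjusted over the list alone), with rises in TP53INP1 (1.53), GADD45A (1.01) and BTG2 (0.85) and falls in PLK2, PLK3, C12orf5 and CDKN1A, the p21 cell cycle inhibitor. Camera gave 0.0158, and an adjusted p = 0.28 with an estimated correlation.

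The remaining lists were not called in RL. Of 31 genes of G1/S and replication, 11 rose, such as GINS2 (0.59) and E2F2 (0.38), while CCND2 and UNG fell (camera adjusted p = 0.159). Homing and adhesion genes went both ways, with 7 of 17 higher and 6 lower. The chemokine receptor CXCR4 rose by 0.79 ± 0.05, from 137 to 237 CPM, S1PR4 rose by 1.64 ± 0.10 and the adhesion receptor CD44 fell by 0.80; camera gave the list an adjusted p of 0.918. Of 33 BCR pathway components 10 rose and 8 fell. CD79B, a signalling chain of the BCR, rose by 1.04 ± 0.05, from 382 to 783 CPM, whereas the phosphatase PTPN6 (SHP-1) fell by 1.67 ± 0.05, from 73.4 to 23.0 CPM, and VAV1 by 0.98; camera gave the list an adjusted p of 0.991. Of 30 interferon response genes 9 rose, among them OAS1 (0.92) and ISG20 (1.03), and 3 fell, DTX3L (-0.75), PARP9 and OAS3 (9 and 5 adjusted over the list alone; adjusted p = 0.118). The list of 7 kinases that ibrutinib binds, BTK among them, had 1 rise and 2 falls (camera adjusted p = 0.817). The BCL2 family gave 7 rises, with the pro-apoptotic BMF at 0.76, and 2 falls, BCL2A1 and BID, among 15 (adjusted p = 0.405). Of 26 ATF4 targets SHMT2 rose and 7 fell, such as the arginine transporter SLC7A1 at -0.67 (2 and 7 adjusted over the list alone; adjusted p = 0.0731). Of 25 proteasome genes 7 fell (adjusted p = 0.119). The counts of rises and falls were 4 and 2 of 24 for glycolysis (adjusted p = 0.859), 5 and 3 of 34 for oxidative phosphorylation (3 and 2 adjusted over the list alone; adjusted p = 0.859), 4 and 1 of 19 for hypoxia (adjusted p = 0.108). They were 6 and 2 of 12 for plasma cell markers (list adjusted p = 0.215), where IRF4 fell by 0.41, 4 and 4 of 13 for germinal center markers (list adjusted p = 0.409), where MME rose by 1.17, and 1 and 1 of 7 for MCL markers (list adjusted p = 0.977). By name, PFKL, SLC2A1, PFKFB3 and ALDOC rose and HK2 and SLC16A1 fell in glycolysis, and SDHA, NDUFA2, NDUFS8, NDUFB8 and UQCRC1 rose and SDHB, SDHD and UQCRFS1 fell in oxidative phosphorylation. In the hypoxia list P4HA2, NDRG1, BNIP3L and SLC2A1 rose and HK2 fell, in the germinal center list STAP1 and BCL7A were among the rises with MME and LMO2, S1PR2, SERPINA9 and ELL3 fell, and in the MCL list CCND1 rose and PON2 fell. The calls of SLC2A1, BNIP3L and HK2 were lost in DESeq2's Wald test (adjusted p = 0.129, 0.186 and 0.277), and that of UQCRFS1 without control replicate 1 or 2 (adjusted p = 0.0687 and 0.0573). Of 14 housekeeping genes SDHA rose and 4 fell, including TFRC, HPRT1 and ACTB (2 and 4 adjusted over the list alone; adjusted p = 0.769); GAPDH had a log2 fold change of 0.14 (adjusted p = 0.0811; called by limma-voom, 0.0356, and with no filter, 0.0323) and ACTB of -0.15 (adjusted p = 0.0477). ACTB lost its call without each RL library in turn (adjusted p from 0.0738 to 0.322). Where no other count is given, here and for JeKo-1, the list alone gave the same counts. No erythroid gene could be tested in RL.

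Some of these lists disagreed within themselves. Median and mean differed in sign for the homing (0.095 and -0.009), BCR component (0.030 and -0.052) and MCL lists (0.034 and -0.032), and for the housekeeping list (0.015 and -0.050, test downward). The test's direction went against both for the germinal center list (-0.025 and -0.042, test upward) and the ibrutinib-bound kinases (0.126 and 0.205, test downward). In fits that left out 1 library, 6 further lists were called. Interferon genes were called higher without control replicate 1 (adjusted p = 1.6e-04) or treated replicate 2 (adjusted p = 2.6e-04), and hypoxia genes without control replicate 2 (1.9e-05) or treated replicate 1 (6.1e-05). ATF4 targets were called lower without control replicate 1 (0.0225) or treated replicate 2 (0.0300), proteasome genes lower without treated replicate 1 (0.0224), glycolysis genes called without control replicate 2 (0.0459), and G1/S genes higher without treated replicate 2 (0.0132). With replicate number as a block, the interferon and hypoxia lists were called higher (camera adjusted p = 0.0146 and 0.0136). DESeq2's Wald test called 2956 genes in RL in place of 4543.

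In treated JeKo-1, RAG1, VPREB1 and MME, genes known from early B-cell development, were higher than in the control. PTPN6 and MS4A1, among the BCR pathway components, were lower. RAG1, the recombinase that rearranges antigen receptor genes, rose with a log2 fold change of 4.43 ± 0.09, from 21.5 to 463 CPM (918 counts in the control and 18167 and 18347 in the treated libraries). The surrogate light chain gene VPREB1 rose by 2.89 ± 0.12 and MME by 2.27 ± 0.09. PTPN6, the phosphatase SHP-1 that dampens BCR signals, fell by 5.39 ± 0.09, from 112 to 2.67 CPM (4812 counts in the control and 91 and 120 in the treated libraries). Its 3 transcripts largely repeat the same reads, so their like counts are not separate evidence. MYC, in contrast to RL, stood at 262 CPM in the control and 247 CPM after treatment, a log2 fold change of -0.08 ± 0.07 (adjusted p = 0.369).

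Of 14050 genes tested in JeKo-1, 3970 changed, 1878 upward and 2092 downward, with 201 rises and 391 falls of at least 2-fold. Rises outnumbered falls at a mean of at least 5 CPM (1540 and 1452) and in DESeq2's Wald test (894 and 687). Most other alternatives kept the excess of falls, such as limma-voom (1824 rises and 2097 falls). The other large rises among genes averaging at least 5 CPM were those of the FOXO-induced C10orf10 (now DEPP1; 3.33 ± 0.10), BTBD3 (2.80 ± 0.08), the chloride channel gene BEST3 (2.59 ± 0.18), the thyrotropin receptor TSHR (2.52 ± 0.20), KLRC4 (2.44 ± 0.20), the phosphatase PTPRE (2.30 ± 0.11) and TMCC2 (2.22 ± 0.14). After PTPN6, the largest falls were those of the pore-forming MPEG1 (-2.92 ± 0.10), the signalling adaptor SLA (-2.85 ± 0.16), the proteoglycan SRGN (-2.65 ± 0.14), the costimulatory ligand CD86 (-2.43 ± 0.14), BASP1 (-2.25 ± 0.15), the lysophospholipase ENPP2 (-2.21 ± 0.14), FCRL5 (-2.11 ± 0.11), the lectin CLEC17A (-2.07 ± 0.11) and the EGR corepressor NAB2 (-2.05 ± 0.08). Apart from RAG1 and PTPN6, whose p-values were smaller than the software can write, the adjusted p-values of these 20 genes ran from 9.0e-247 to 5.8e-33. The prior degrees of freedom were infinite in this fit, against 9.4 in RL. Each gene's spread was thus taken from the trend over all genes, and such small p-values do not measure how well a single gene repeats. CCND1 had a log2 fold change of 0.10 (adjusted p = 0.277; called with GC and length trends removed, at 0.151, adjusted p = 7.9e-05), BTK of 0.01 (adjusted p = 0.932) and BCL6 of -0.10 (adjusted p = 0.844).

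Of 32 BCR pathway components in JeKo-1, 19 fell and 6 rose (19 and 7 adjusted over the list alone), with a camera adjusted p of 4.5e-17, and an adjusted p = 0.212 with an estimated correlation. PTPN6, the coreceptor CD72 (-1.90 ± 0.07), MS4A1 (-1.75 ± 0.06, from 281 to 83.4 CPM) and VAV1 (-1.60) fell, whereas CD79B rose by 0.89 ± 0.07, from 308 to 571 CPM. Of 29 immediate early genes 16 fell and 0 rose, also adjusted over the list alone, among them DUSP2 (-1.44), IER2 (-1.06), IER5 (-0.84), EGR2 (-2.92 ± 0.36) and CCL3 (-2.39 ± 0.32). Camera gave 8.4e-09, and an adjusted p = 0.22 with an estimated correlation. CCL4 fell by 0.71 ± 0.20 (adjusted p = 0.00208) and was not called by DESeq2's Wald test (adjusted p = 0.311), and EGR1 had a log2 fold change of -0.80 ± 0.40 (adjusted p = 0.125). Of 25 NF-kB targets 15 fell, such as RILPL2 (-1.57) and CD83 (-1.36), and 3 rose, the apoptosis inhibitors BIRC3 (1.26) and BCL2L1 (0.43) and the transcription factor IRF4 (0.51), with 15 and 4 adjusted over the list alone. Camera gave 3.8e-04, and an adjusted p = 0.34 with an estimated correlation. Of 26 interferon response genes 13 fell, such as the antiviral GTPase MX1 (-1.42), PARP9 (-1.34) and DTX3L (-0.91), and 3 rose, ISG20, MX2 and STAT2 (14 and 3 adjusted over the list alone). Camera gave 2.2e-05, and an adjusted p = 0.482 with an estimated correlation.

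In JeKo-1, 21 of 31 genes of G1/S and replication rose, such as E2F2 (0.52), UNG (0.45) and GINS2 (0.44), while CCND2 and CCNE1 fell (22 and 3 adjusted over the list alone). Camera gave 1.2e-05, and an adjusted p = 0.369 with an estimated correlation. Of 30 mitotic genes 17 rose and 0 fell, also adjusted over the list alone, with BUB1 at 0.79, CENPF at 0.78 and CENPE at 0.49. Camera gave 1.3e-07, and an adjusted p = 0.33 with an estimated correlation. Of 19 replication histones 16 rose and 0 fell, also adjusted over the list alone, such as HIST1H2AG (0.35). Camera gave 3.0e-06, and an adjusted p = 0.369 with an estimated correlation. Of 29 FOXO targets 11 rose, including RAG1, CCNG2 (0.85) and YPEL5 (0.39), and FOXO1 and KLF6 fell (13 and 2 adjusted over the list alone). Camera gave 1.7e-06, and an adjusted p = 0.225 with an estimated correlation. TXNIP rose by 0.21 ± 0.07 (adjusted p = 0.0177), a call lost in DESeq2's Wald test (adjusted p = 0.215) and without treated replicate 1 (0.0922). Of 34 oxidative phosphorylation genes 10 rose by small amounts and 0 fell, also adjusted over the list alone (median 0.121). Camera gave 0.00688, and an adjusted p = 0.482 with an estimated correlation.

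In JeKo-1, 15 of 21 endoplasmic reticulum stress genes fell, such as PDIA3 (-0.55) and DNAJB11 (-0.53), and 2 rose, EDEM1 (0.62) and ERN1 (15 and 3 adjusted over the list alone). Camera gave 1.5e-05, and an adjusted p = 0.369 with an estimated correlation. Of 23 cholesterol synthesis genes 9 fell, such as STARD4 (-0.70), HMGCS1 (-0.40) and CYP51A1 (-0.39), and 2 rose, including MSMO1, also adjusted over the list alone. Camera gave 0.0114, and an adjusted p = 0.369 with an estimated correlation. Of 18 heat shock genes 10 fell, such as HSPA1B (-0.90), which shares near-identical sequence with HSPA1A, and HSPH1 (-0.45), and HSPA4 rose, also adjusted over the list alone. Camera gave 0.00894, with an adjusted p = 0.482 with an estimated correlation and 0.0545 without treated replicate 2.

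Differentiation and homing lists held strong changes in both directions in JeKo-1. Of 12 plasma cell markers 5 rose, such as the joining chain gene IGJ (1.82), TNFRSF17 (1.35) and CD38 (0.96), while SDC1 and FKBP11 fell (5 and 3 adjusted over the list alone). Camera gave 0.00242, with an adjusted p = 0.22 with an estimated correlation and 0.0594 without treated replicate 2. Of 14 germinal center markers 5 rose, including MME, GCET2 (1.42) and BACH2 (1.19), and 3 fell, SERPINA9, LMO2 and ELL3 (5 and 4 adjusted over the list alone). The test went upward (adjusted p = 1.2e-05) with a median of 0.031 and a mean of -0.171. It had an adjusted p = 0.212 with an estimated correlation, and 0.4 and 0.212 without treated replicate 1 and 2. Of 15 homing genes 5 rose, including CXCR4 (1.03 ± 0.07, from 500 to 1018 CPM), S1PR4 (2.06 ± 0.13) and the oxysterol receptor GPR183 (1.04), and 3 fell, CXCR5, ITGB2 and CCR2 (5 and 4 adjusted over the list alone). That test also went upward (adjusted p = 0.0179) with a median of 0.064 and a mean of -0.123. It had an adjusted p = 0.482 with an estimated correlation. In a model of all 7 libraries, also used when a JeKo-1 library was left out, the adjusted p was 0.146 with every library kept, and 0.497 and 0.337 without treated replicate 1 and 2. Of 6 kinases that ibrutinib binds, ERBB4 (2.15) and BLK rose and ERBB2 and JAK3 fell, also adjusted over the list alone (adjusted p = 0.00351; adjusted p = 0.33 with an estimated correlation, and 0.473 and 0.722 without treated replicate 1 and 2). The calls of ERBB2 and BLK were lost in DESeq2's Wald test (adjusted p = 0.188 and 0.307). ERBB2 also lost its call without treated replicate 1 (adjusted p = 0.0754) or 2 (0.0818). BLK lost its call in the 7-library model with every library kept (adjusted p = 0.0612) and without treated replicate 2 (0.216), with no filter (0.0715) and at a minimum of 5 CPM (0.0643).

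The genes of the MYC-linked ribosome production list were not called as a list in JeKo-1. Of 35, 3 rose (GNL3, NHP2 and NPM1) and 5 fell (RRS1, SRM, MYBBP1A, IPO4 and POLR1B), with a median of -0.011 (camera adjusted p = 0.867). Without treated replicate 1, the falls of SRM and MYBBP1A were no longer called (adjusted p = 0.247 and 0.237), nor were they in DESeq2's Wald test (0.199 and 0.121). For the other lists that were not called, the rises and falls were 8 and 7 of 24 p53 targets, with GADD45A at 1.46, TP53INP1 at 1.47 and MDM2 at 0.60 (8 and 8 adjusted over the list alone; adjusted p = 0.181). They were 4 and 6 of 24 glycolysis genes (5 and 6 adjusted over the list alone; adjusted p = 0.901), 4 and 6 of 26 ATF4 targets (adjusted p = 0.425), and 4 and 5 of 18 hypoxia genes (5 and 5 adjusted over the list alone; adjusted p = 0.901). They were 2 and 1 of 25 proteasome genes (1 and 1 adjusted over the list alone; adjusted p = 0.5), 3 and 2 of 13 BCL2 family genes (adjusted p = 0.867), and 0 and 3 of 8 MCL markers, DBN1, PON2 and FMOD (adjusted p = 0.473). Of 14 housekeeping genes 4 rose, including RPLP0, PPIA and SDHA, and 2 fell, YWHAZ and ACTB (list adjusted p = 0.867), with ACTB at -0.47 and GAPDH at 0.14 (adjusted p = 0.178; called by limma-voom, 0.0415, and with GC and length trends removed, 7.8e-16). By name, PFKP, PDK1, LDHB and SLC16A1 rose in glycolysis, VLDLR, CHAC1, ATF4 and CEBPG among ATF4 targets, NDRG1, EGLN3, BNIP3L and PDK1 in the hypoxia list, PSMA2 and PSMB7 in the proteasome, and HRK, BCL2L1 and BMF in the BCL2 family. P4HA1, HK2, ERO1L, EGLN1 and KDM3A fell in the hypoxia list, PSMD11 in the proteasome, and BIK and BID in the BCL2 family. The calls of BMF, BID, BNIP3L, P4HA1, PSMB7 and PSMD11 were lost in DESeq2's Wald test (adjusted p = 0.282, 0.388, 0.0749, 0.174, 0.217 and 0.128). In the 7-library model with every library kept, BID (adjusted p = 0.0757), HK2 (0.0839), BNIP3L (0.121), P4HA1 (0.204) and PSMB7 (0.0749) were not called. In the same order they had adjusted p of 0.364, 0.313, 0.376, 0.351 and 0.257 without treated replicate 1, and 0.0557, 0.26, 0.195, 0.511 and 0.0579 without treated replicate 2. PSMA2 was called in that model and lost its call without treated replicate 1 (adjusted p = 0.0735), as did BMF (0.0673), PFKP (0.0575) and PSMD11 (0.104) without treated replicate 2. With no filter BID (adjusted p = 0.0708) and PSMB7 (0.0687) were not called, and PSMB7 was not called in most alternatives, with adjusted p from 0.0504. Median and mean differed in sign for glycolysis (0.008 and -0.101), hypoxia (-0.009 and 0.006) and MCL markers (0.060 and -0.356). The test in JeKo-1 rests on 1 residual degree of freedom between its 2 treated libraries, with 1 spread trend for all genes, and assumes that the lone control varies like them. DESeq2's Wald test called 1581 genes in place of 3970, 894 higher and 687 lower, and the 7-library model called 3521 with every library kept and 2397 without treated replicate 1.

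**Figure D1:**
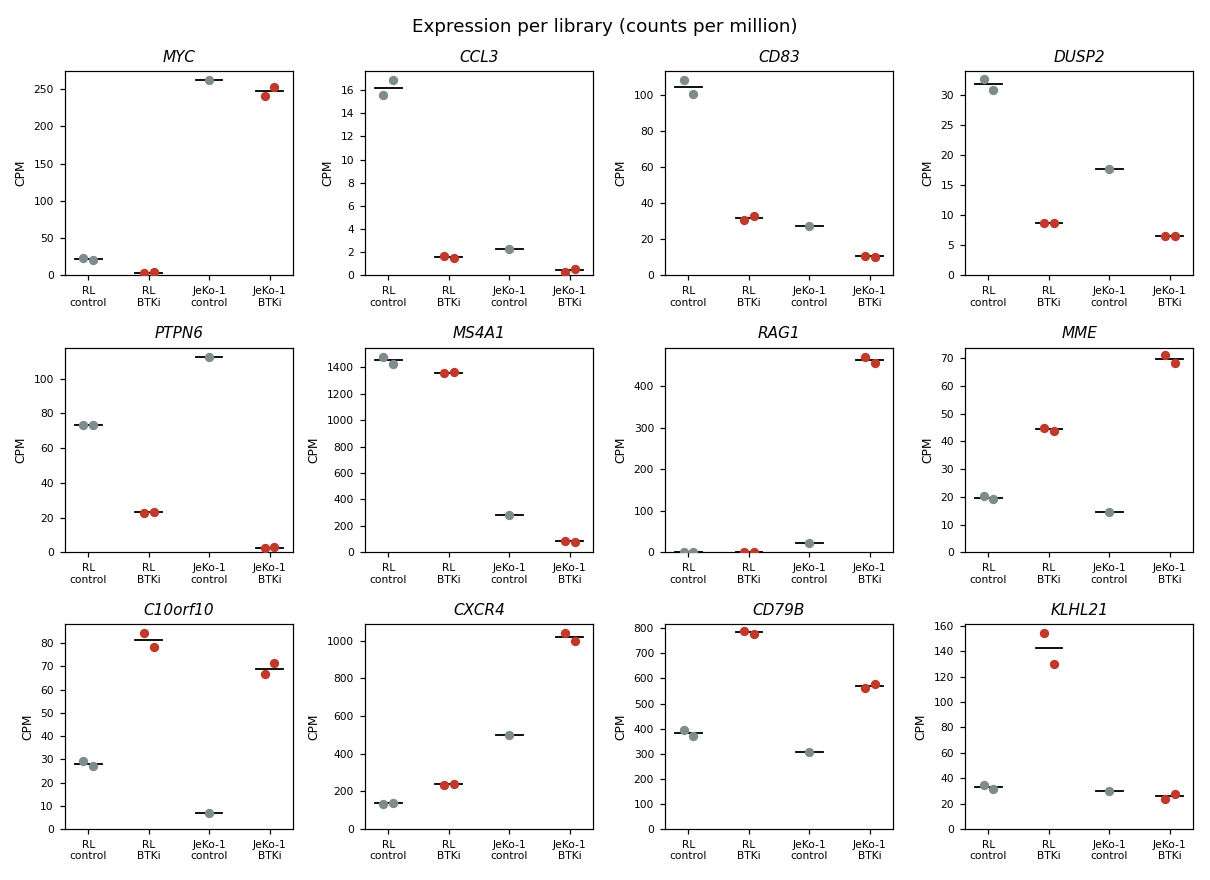
Expression in library-scaled counts, CPM (y axis, linear from 0) of 12 genes in each of the 7 libraries, with controls in grey, BTK inhibitor in red and group means as black lines. MYC falls from 22.3 to 3.76 CPM in RL and stands at 262 and 247 CPM in JeKo-1, while PTPN6 falls in both lines and RAG1 reaches 463 CPM in treated JeKo-1.

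PTPN6, DUSP2 and CD83 fell in both lines, and the responses of PTPN6, MYC and MS4A1 differed between them. Over 13394 genes tested in both, log2 fold changes correlated with Pearson r = 0.310 and Spearman rho = 0.273, across genes, which are not independent replicates. The lines share no control library. Of 1671 genes called in both, 1355 (81.1%) changed in the same direction. Genes higher in both numbered 665, against 282 for independent lists (Fisher's exact test, two-sided, odds ratio 4.16, p = 4.6e-129), and genes lower in both 690, against 319 (odds ratio 3.61, p = 5.8e-112). Among genes averaging at least 5 CPM in each line, the largest changes held by both lines were those of PTPN6, S1PR4, C10orf10 (1.53 ± 0.06 in RL), TP53INP1, DUSP2, CD83, the phosphatase PTPRJ (-1.25 ± 0.08 in RL and -1.55 ± 0.08 in JeKo-1) and the vitamin D receptor VDR (1.23 ± 0.09 and 1.92 ± 0.18).

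**Figure D2:**
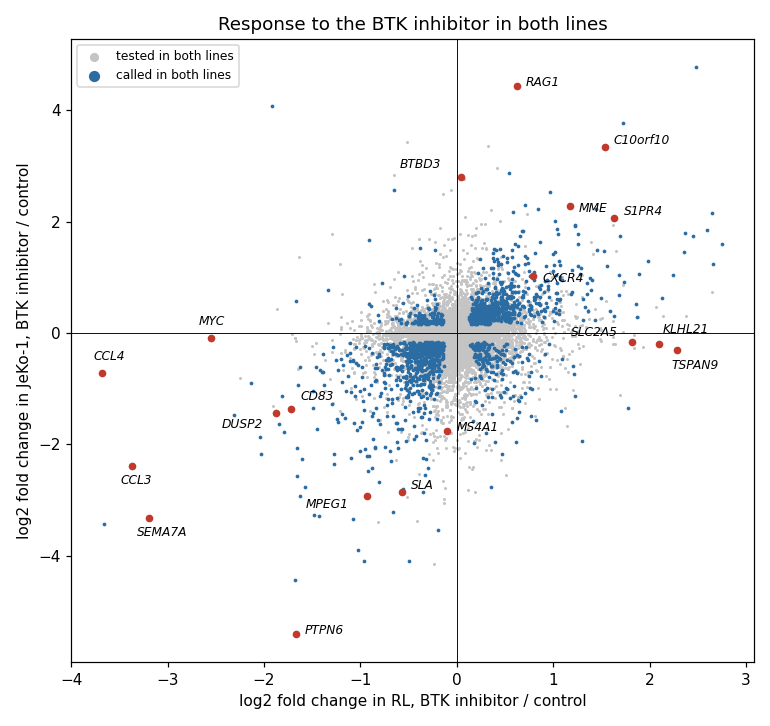
Log2 fold change with the BTK inhibitor in RL (x axis) against that in JeKo-1 (y axis) for the 13394 genes tested in both lines, one point per gene; blue points are the 1671 genes called in both and labelled red points are named genes. PTPN6 lies lowest for JeKo-1 at -5.39, and MYC lies at -2.55 for RL and -0.08 for JeKo-1.

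Tested in a model of all 7 libraries, the effect of the inhibitor differed between the lines for 2815 of 15845 genes, with JeKo-1 minus RL above 0 for 1397 and below 0 for 1418. Of these, 316 were called in opposite directions in the lines, 134 lower in RL and higher in JeKo-1, and 182 higher in RL and lower in JeKo-1. Among genes at 5 CPM or more in both lines, the differences with the smallest p were those of PTPN6 (-3.71 ± 0.12, adjusted p = 9.4e-14), BTBD3 (2.77 ± 0.13), MPEG1 (-1.97 ± 0.09), MYC (2.47 ± 0.12, adjusted p = 6.2e-11), MS4A1 (-1.64 ± 0.08), the T- and B-cell adaptor SIT1 (-1.73 ± 0.09), CLEC17A (-1.95 ± 0.10) and SLC2A5 (-1.97 ± 0.11). In RL, BTBD3 had a log2 fold change of 0.04 (adjusted p = 0.820) and MS4A1 of -0.10 (adjusted p = 0.159). SIT1 fell by 1.58 in JeKo-1, and in RL had 0.17 (adjusted p = 0.0216), a call lost in DESeq2's Wald test (0.0883) and without either control library (0.0851 and 0.204) or treated replicate 2 (0.0610), and with GC and length trends removed (0.0791). IRF4 fell in RL and rose in JeKo-1 (difference 0.93, adjusted p = 7.0e-08), and MX1 rose by 0.65 ± 0.12 in RL and fell in JeKo-1 (difference -2.06, adjusted p = 4.3e-07).

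By list, the genes of the ribosome production list had the smallest camera p of the difference. The response of 34 of 35 was higher in JeKo-1 than in RL and 0 were lower (35 and 0 adjusted over the list alone). Camera's adjusted p was 1.1e-43, and 0.165 with an estimated correlation. BCR components had 19 of 33 responses lower in JeKo-1 and 3 higher, BTK, SYK and PRKCB (21 and 5 adjusted over the list alone; adjusted p = 4.0e-20, and adjusted p = 0.165 with an estimated correlation). Interferon genes had 14 of 30 lower and 0 higher (18 and 0 adjusted over the list alone; adjusted p = 7.1e-10, and adjusted p = 0.605 with an estimated correlation). Heat shock genes had 8 of 18 higher and HSPA6 and HSPA1B lower (9 and 2 adjusted over the list alone; adjusted p = 1.3e-04, and adjusted p = 0.605 with an estimated correlation). Smaller camera calls were those of cholesterol synthesis, with 8 of 24 higher and 2 lower, LSS and SREBF2 (9 and 3 adjusted over the list alone; adjusted p = 0.0371, and adjusted p = 0.605 with an estimated correlation), and of FOXO targets, with 8 of 31 lower and RAG1 higher (10 and 2 adjusted over the list alone; adjusted p = 0.0457, and adjusted p = 0.605 with an estimated correlation). Plasma cell markers had 5 of 12 higher and PRDM1 and DERL3 lower (6 and 3 adjusted over the list alone; adjusted p = 0.0220, and adjusted p = 0.572 with an estimated correlation). Proteasome genes had 6 of 25 higher and oxidative phosphorylation genes 3 of 34, UQCRFS1, ATP5G1 and SDHB, with 0 lower in each and the same counts adjusted over the list alone (0.0220 each, and adjusted p = 0.65 with an estimated correlation for each). Median, mean and test differed in sign for the endoplasmic reticulum stress, p53, germinal center and homing lists, whose differences were not called (adjusted p = 0.179, 0.416, 0.179 and 0.430).

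**Figure D3:**
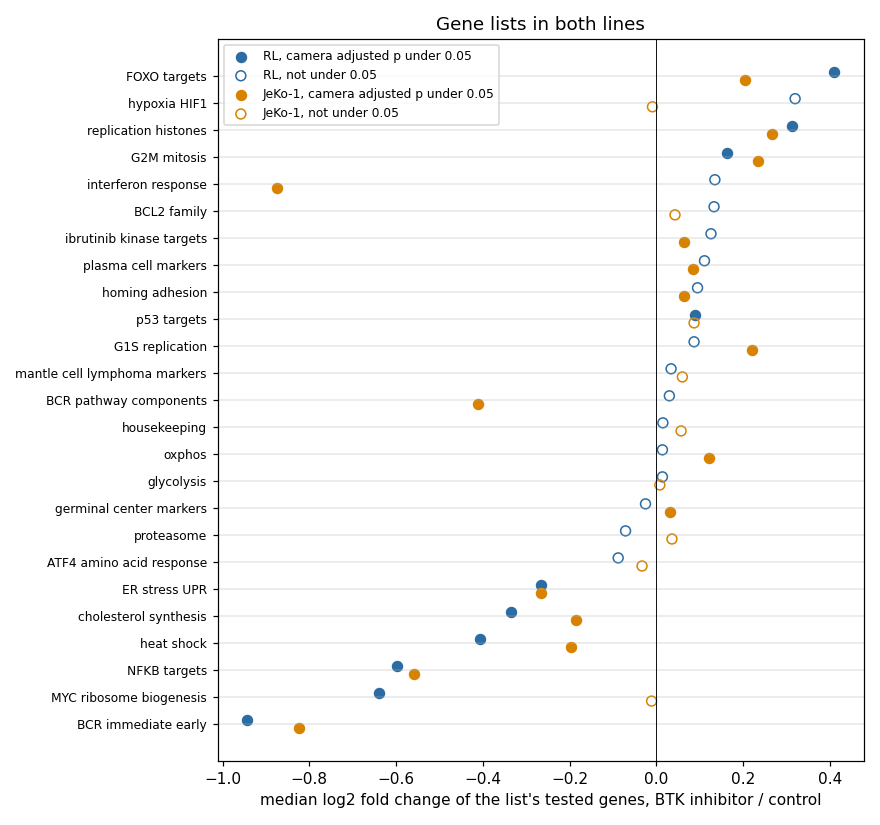
Median log2 fold change with the BTK inhibitor (x axis) of each gene list tested by camera (y axis), in RL (blue) and JeKo-1 (orange), with filled circles for a camera adjusted p under 0.05 and open circles otherwise; with an estimated correlation no list is called (adjusted p of at least 0.0871). Genes of the MYC-linked ribosome production list lie at -0.639 in RL and -0.011 in JeKo-1, whereas immediate early genes lie at -0.944 and -0.825.

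The authors' deposited comparison of RL gave 8165 transcripts at p under 0.05, 4275 higher and 3890 lower, and 5292 at a false discovery rate (FDR) under 0.05. At an absolute fold of at least 1.5 it held 4575 transcripts in RL and 5686 in JeKo-1, where its table gives ratios without p-values, and at 2-fold 1582 and 2934. Of the transcripts past that FDR in RL, 5266 were tested here, and all 5266 (100%) had the same direction, with 5246 (99.6%) called. Across transcripts, the deposited log2 ratios and those fitted here had Pearson r of 0.9987 in RL and 0.9855 in JeKo-1.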

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

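The tests of scaling, of GC content and transcript length, the test of shared direction among genes called in both lines, and the spread over RL library pairs used for genes called in JeKo-1 alone, were chosen only after the results were seen.

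These results stood out because the response to the same inhibitor differed between the lines in the model of all 7 libraries. The effect of the inhibitor differed between the lines for 2815 genes. Opposite directions were called for 316 genes. PTPN6 fell more in JeKo-1 than in RL, with a difference of -3.71. BTBD3 differed by 2.77, rising in JeKo-1. MPEG1 differed by -1.97. MYC differed by 2.47. MS4A1 differed by -1.64. SIT1 differed by -1.73. CLEC17A differed by -1.95. SLC2A5 differed by -1.97. Lists whose camera test of the difference passed were ribosome production (adjusted p = 1.1e-43), BCR components (4.0e-20), interferon response (7.1e-10), heat shock (0.00013), oxidative phosphorylation, proteasome and plasma cell markers (0.022 each), cholesterol synthesis (0.0371) and FOXO targets (0.0457), each with an adjusted p of at least 0.165 with an estimated correlation.

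The large changes in JeKo-1, such as the 463 CPM of RAG1 after treatment, rest on 1 control library. RL RNA in the treated libraries is argued against, since 38 genes at 50 CPM or more in RL controls and at most 1 CPM in the JeKo-1 control had a median of 0.0267% of their RL level after treatment. A different cell line is also argued against, since 4 genes lay at least 8-fold apart between treated and control JeKo-1 against 626 between the controls of the lines (0.639%). That count took genes at 5 CPM or more in either group, with 0.5 CPM added to each level, so it is smaller than a count from the fitted changes. GC content or transcript length as the whole cause is argued against because 566 of 566 genes changed at least 2-fold (100%) kept their call with those trends removed. A technical shift of the control unrelated to the RL response is argued against as the main source of direction among genes called in both lines. Of these as a set, 81.1% moved the same way as in RL and 316 the opposite way. This count of signs does not cover single genes or the size of a change, which still rest on the lone control. For genes called in JeKo-1 and not in RL, 62.5% (1345 of 2151) had the same sign in RL, ranging from 56.7% to 64.0% over the 4 pairs of RL libraries, which spans the 60% written beforehand as the bound, so a shift of the lone control and a response particular to JeKo-1 cannot be told apart for them. Of the 233 among them that changed at least 2-fold in JeKo-1, 137 (58.8%) had the same sign in RL. A line-specific response to the inhibitor stays open as a biological explanation that 1 control cannot test.

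KLHL21, ZBTB48 and TAS1R1, neighbours in the GRCh38 annotation with KLHL21 on the opposite strand to the other pair, rose together in RL by 2.10, 1.87 and 3.33 on the log2 scale. GC content or length is argued against, as the smallest of these was 1.83 with the trends removed. Read-through from KLHL21, counted without strand, may add reads to ZBTB48 and TAS1R1; the bound written beforehand, extra reads per kilobase in either exceeding those of KLHL21, was met by ZBTB48 at 106% (103% to 108% over library pairs, TAS1R1 at 12.5%), but that bound assumed even coverage between transcripts, which counts per transcript cannot show, and was exceeded by a small margin. Neighbours were then counted for the 68 genes raised at least 2-fold in RL that averaged at least 5 CPM, without leaving out this locus. Within 20 kilobases, 13 of 24 neighbours on the 3' side were called higher against 11 of 23 on the 5' side (Fisher's exact test, two-sided, p = 0.773). Both shares, 54.2% and 47.8%, lay above the 15.1% of all tested RL genes that were called higher, a gap whose cause was not tested. Read-through and a shared induction by the inhibitor cannot be told apart without strand or coverage along the genes.

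MYC and all 35 genes of the ribosome production list fell in RL, with a list median of -0.639, while the list stood at -0.011 in JeKo-1. A scaling factor moves every gene alike, so scaling between libraries is argued against by the list's median differing by -0.647 from that of all other genes. The standard error of the list's median, 0.05, was taken across its genes as if independent, although their estimated correlation was 0.356. It does not measure spread between libraries. GC content or length is argued against, since the list's median was -0.628 with those trends removed and 35 of 35 genes stayed called lower. A candidate explanation is a response that follows the fall of MYC in RL, whereas MYC stood at 247 CPM in treated JeKo-1; this is a hypothesis from the same data and no experiment here separates MYC from other BTK-dependent signals.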

How the results depend on the processing

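The transcript flagged by the authors and the removal of GC and length trends were tested only after the results were seen. Counts of called genes ran from 3345 to 5601 in RL and from 2397 to 4763 in JeKo-1 over the alternatives other than DESeq2's Wald test and a 2-fold minimum, and from 1893 to 3241 for the difference over all of its alternatives. DESeq2's Wald test called 2956 genes in RL and 1581 in JeKo-1; the cause was not tested. The difference was above 0 for 1609 genes and below 0 for 1312 with DESeq2 size factors, and for 1121 and 772 with the Wald test. A minimum of 2-fold left 427 and 592, by construction. Leaving out 1 library gave 3345 to 4326 in RL, 2397 to 2931 in JeKo-1, where the same 7-library model called 3521 with every library kept, and 1947 to 2872 for the difference. With a minimum of 5 CPM the correlation between the lines was 0.379, and with a prior count of 5 it was 0.327, since a prior count shrinks the folds of low-count genes by construction; the cause of the former was not tested. With an estimated correlation 0 lists were called in RL and 0 in JeKo-1 by camera, against 10 and 16 with the preset one. In RL the estimates of the NF-kB, immediate early and p53 lists were -0.03, -0.002 and -0.039, below the preset 0.01. Higher correlation among their genes thus does not account for those losses. That version of the test has only the residual degrees of freedom of the fit, 2 in RL and 3 in the 7-library model used for JeKo-1. So few degrees of freedom raise the p of every list, whatever its correlation. The other called RL lists had estimates from 0.057 to 0.356. How much correlation added to the losses was not tested for them or in JeKo-1. At an unadjusted p under 0.05 the test with an estimated correlation passed 3 and 5 lists, and fry, whose p tests whether a list's genes move on balance one way, called 13 and 0 after adjustment. Leaving out a library gave 12 to 13 lists in RL and 11 to 13 in JeKo-1. The authors' table held 8165 RL transcripts at p under 0.05. With a limit on fold in place of p it held 4575 at 1.5-fold and 1582 at 2-fold, and those past both FDR under 0.05 and the fold were 2017 and 764.

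The replicate block gave 4416 genes in RL (4290 of the 4543 kept) and 12 lists, which added the interferon (adjusted p = 0.0146) and hypoxia (0.0136) lists; FN1 (0.0516) and ACTB (0.0563) were not called. Across all genes the replicate numbers gave no sign of pairing in RL, with a correlation of deviations of -0.008 (-0.047 at 5 CPM or more). Both added lists did differ alike by replicate number. Summed interferon genes stood at 907.8 and 790.2 CPM in control replicates 1 and 2, and at 1074 and 913.3 CPM in treated ones. Hypoxia genes stood at 321.5 and 427.3 CPM, and at 362.1 and 497.8 CPM. A shared replicate effect in these lists stays possible. No paired test was possible in JeKo-1 with its 1 control.

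Of 1381 values of named genes in RL, 1358 stayed on the same side of the threshold in the same direction, 21 lost and 2 gained the call; of 1127 in JeKo-1, 1071 stayed, 52 lost and 3 gained it, and 1 reversed, COX7B, at -0.021 (adjusted p = 0.762) with GC and length trends removed against 0.21; the cause was not tested. All 80 for the difference stayed. Those genes, and most other named genes, were chosen for a small p or a large change in these same data. Their tallies therefore do not show how stable the other calls are. Of all called genes, DESeq2's Wald test kept 2956 of 4543 in RL, 1578 of 3970 in JeKo-1 and 1866 of 2815 for the difference. Of list values, 165 of 189 stayed in RL (10 lost, 14 gained) and 75 of 100 in JeKo-1 (25 lost). The list tallies cover different alternatives, with fry and the replicate block counted for RL only and the 7-library model with every library kept for JeKo-1 only. At this depth and replication a log2 change of 0.25 was mostly missed in simulated data.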

Other observations

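Of the immediate early list, SPRY2, SPRED1, SPRED2 and ETV5 fell in both lines; they were chosen after their values were seen, and no explanation was tested. SPRY2, which restrains receptor tyrosine kinase signals, had log2 fold changes of -2.04 ± 0.28 in RL and -1.87 ± 0.47 in JeKo-1. The related SPRED1 had -0.97 ± 0.14 and -1.38 ± 0.24, and SPRED2 had -0.92 ± 0.18 and -2.47 ± 0.31, a difference between the lines with an adjusted p of 0.00435. The transcription factor ETV5 had -1.03 ± 0.14 and -3.90 ± 0.96, with an adjusted p of 0.013 for the difference. The phosphatase DUSP5 fell by 2.04 ± 0.24 in JeKo-1, while in RL it stood at 78.1 CPM in controls and 76.0 CPM after treatment (difference -1.99, adjusted p = 4.0e-07).

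RAG2, the partner of RAG1 in the recombinase, rose with it in JeKo-1, from 0.210 to 4.75 CPM (log2 fold change 4.48 ± 0.33), and was too low to test in RL. The germinal center genes SERPINA9 and LMO2 fell in JeKo-1 by 4.10 ± 0.75 and 2.77 ± 0.71 while MME, GCET2 and BACH2 rose. The chemokine receptor CXCR5 and the integrin chain ITGB2 fell in both lines, by 0.69 ± 0.06 and 0.93 ± 0.09 in RL and by 2.30 ± 0.29 and 2.21 ± 0.31 in JeKo-1, from control levels of 2.57 and 2.24 CPM in the latter. TNF fell in RL from 4.11 to 0.145 CPM (-4.60 ± 0.31).

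Around KLHL21 in RL, NOL9, which lies beyond ZBTB48 and TAS1R1, rose by 0.83 ± 0.07 and PHF13, which overlaps the 5' end of KLHL21, by 0.66 ± 0.09, while THAP3 had a log2 fold change of -0.04 (adjusted p = 0.728) and DNAJC11 fell by 0.22 (adjusted p = 0.00595). In JeKo-1 the same region had log2 fold changes of 0.06 for NOL9, 0.28 for ZBTB48 (adjusted p = 0.0264), -0.20 for KLHL21 (adjusted p = 0.0589) and -0.20 for PHF13 (adjusted p = 0.35). These neighbours were chosen after the values of KLHL21 were seen.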
